A study of Homo sapiens with 9 samples.

How the data were processed

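RNA was measured by sequencing in 9 libraries of 22Rv1 cells in which PDCD4 was depleted with a short hairpin RNA and WT, S239A or S239D PDCD4 was put back, 3 libraries per group. Total RNA was purified on columns, messenger RNA was selected on poly-T beads and complementary DNA was primed with random hexamers, per the labels' protocols. Strandedness was not given in the sources used here.

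The authors deposited expected counts per gene, estimated by RSEM, with no normalization between libraries. They also deposited TPM, a measure of transcript abundance scaled within each library by the authors. Trimmomatic 0.39 and RSEM are named in the submitters' processing notes, without their settings. The aligner, genome build and annotation release were not given in the sources used here. Coordinates are those of the deposited count table. Of its gene identifiers 96.52% were found in GENCODE release 29, of which 99.93% overlapped the reference gene on GRCh38 and 92.94% shared a gene end with it.

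The count table listed 60623 genes, of which 31890 had no count in any library, and 3.8% of its values were not whole numbers. Expected counts were rounded to whole numbers. Genes without a symbol (22747) held 1.33% of counts and were kept in the tests. Total counts per library were 9215664, 5696841 and 8853099 in WT, 8072064, 8575872 and 9688554 in S239A, and 8058207, 8077525 and 9449064 in S239D. A floor of 3 counts was 0.307 to 0.527 CPM, covering counting error only. The correlation of log2 CPM between libraries, across genes, which are not independent replicates, was 0.976 to 0.987 within groups and 0.937 to 0.985 between groups.

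Groups followed the genotype labels. Counts were scaled by TMM and filtered with filterByExpr, which left 16213 genes. They were tested with edgeR 4.0.16 in R 4.3.3, by two-sided quasi-likelihood F tests in 1 fit of all 9 libraries with group means. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. The common biological coefficient of variation was 0.11. S239A and S239D were each compared with WT and with each other, and the last comparison tests whether S239A and S239D differ from WT by unlike amounts. Log2 fold changes are edgeR's, with SE and 95% intervals, and group levels are mean normalised CPM with SD.

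The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were PDCD4, PLK1, MYC, EIF4A1, EIF4A2 and UGT2B15, with UGT2B17 if measured, which did not pass the filter. For each comparison they also included the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 5 CPM and no overlap between groups. The 4 called members with the smallest adjusted p of each called list and called markers of other cell types completed the rule. Some genes that the rule chose are not reported here, and no others took their place. Of 35 fixed lists, 32 had at least 5 tested members and were tested with camera (preset correlation 0.01, limma 3.58.1), adjusted over those lists. The counts of called members are given over all genes and adjusted over the list alone.

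On simulated data with 200 changed genes, drawn from the real means and library sizes, the S239A against WT comparison (15825 genes) recovered 52.2% of genes changed 1.5-fold, 73.1% of those changed 2-fold and 93.9% of those changed 4-fold, and 14 of its 160 calls were unchanged genes. The overlap of the variants' effects was set against 20 simulated sets. In these, unchanged groups were compared with the same simulated WT libraries, and all groups had the same spread per gene.

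The alternatives were RLE scaling, DESeq2 1.42.0, limma on log2(TPM + 1) for genes with at least 1 TPM in 3 libraries, no filter, a filter of 1 CPM in 6 libraries, fits of the compared groups alone, the replicate number as a block, and each library left out in turn. Camera was rerun with an estimated correlation and set beside fry. Leaving out both replicate 2 libraries of the variants, removing trends over GC content and transcript length, and thinning all libraries to one total were added after seeing the data.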

Results

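Gene expression was measured by RNA sequencing in 22Rv1 cells, a human prostate carcinoma line. PDCD4, a tumour suppressor that binds and inhibits the translation initiation helicase EIF4A, was depleted with a short hairpin RNA. One of 3 forms of the protein was then put back. These were the wild type (WT), S239A, in which alanine replaces a serine and cannot be phosphorylated, and S239D, in which aspartate mimics a phosphate at the same position. The study asks how phosphorylation of PDCD4 by the mitotic kinase PLK1 bears on resistance to the antiandrogen enzalutamide. Each form had 3 libraries, 9 in all, with 5696841 to 9688554 counts per library. Parental cells and cells with the knockdown alone were not analysed here. The labels do not say that the libraries of a group came from separate cultures or separately made lines, so the p-values measure only the spread between these samples, which may be technical.

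The 3 S239D libraries stood far from the other 6. The first principal component of log2 CPM (counts scaled to library size) held 56.8% of the variance, and S239D lay at 55.2 to 58.7 on it, against -33.5 to -24.7 for WT and S239A. S239A replicate 2 and S239D replicate 2 stood apart from the other libraries of their groups on the second component (10.9% of the variance), at -35.8 and -27.3. Those 2 libraries also had the highest share of counts from the mitochondrial genome within their groups, 5.38% and 6.01%. That share was 2.95 ± 0.11% in WT, 3.9 ± 1.3% in S239A and 5.21 ± 0.70% in S239D (SD, n = 3). Transcripts of cytosolic ribosomal proteins took 5.83 ± 0.071%, 5.66 ± 0.39% and 4.27 ± 0.32% of counts in the same order.

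**Figure D1:**
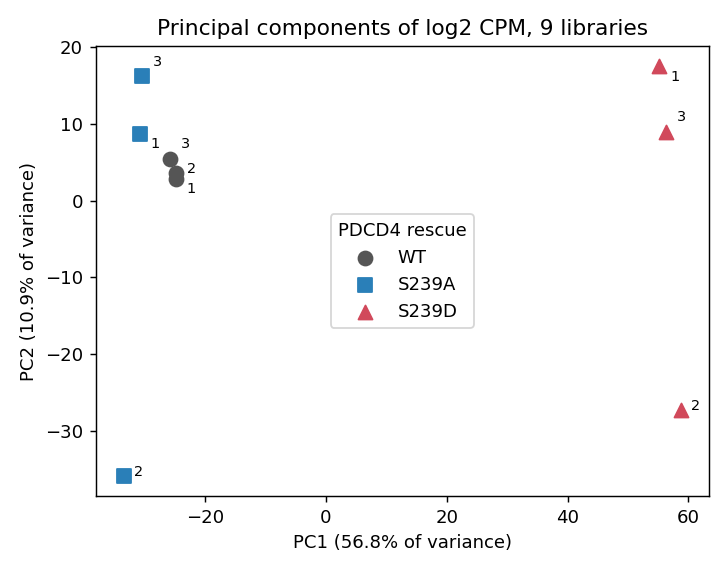
Each point is a library, placed by the first (x axis) and second (y axis) principal components of log2 CPM; symbols and colours give the PDCD4 form and the digit is the replicate number. The S239D libraries lie at 55.2 or above on the first component and the other 6 at -24.7 or below.

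PDCD4 itself (chromosome 10, 110871795 to 110900006) was read first, since it is the gene that was depleted and put back. Its counts can hold reads from both the cells' own gene and the introduced copy, which were not told apart. PDCD4 stood at 23.1 ± 2.4 CPM in WT, 22.4 ± 3.1 in S239A and 17.0 ± 0.18 in S239D (SD, n = 3). It was lower in S239D than in WT, with a log2 fold change of -0.44 (SE 0.13, edgeR adjusted p = 0.0164), and lower than in S239A by a log2 fold change of -0.40 (SE 0.13, edgeR adjusted p = 0.0245). S239A and WT were not told apart (-0.040, 95% interval -0.32 to 0.24, edgeR adjusted p = 0.953). The call against WT was lost without WT replicate 1 (edgeR adjusted p = 0.0657), without WT replicate 2 (edgeR adjusted p = 0.0627) and with limma on log2(TPM + 1) (-0.29, adjusted p = 0.41), and over all alternatives the adjusted p ran from 0.00878 to 0.41. The call against S239A was lost without S239A replicate 3, S239D replicate 1 or S239D replicate 3, with DESeq2 (adjusted p = 0.0539) and with limma on log2(TPM + 1) (-0.20, adjusted p = 0.585), with a range of 0.0122 to 0.585.

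The comparison of S239A with WT asks what losing the phosphorylation site does. TXNIP, which encodes an inhibitor of thioredoxin and of glucose uptake (chromosome 1, 145992435 to 145996579), was the only gene of 16213 to pass the test. It fell from 468 ± 16 CPM in WT to 251 ± 13 in S239A (SD, n = 3), a log2 fold change of -0.90 (SE 0.074, edgeR adjusted p = 9.79e-05). MYC stood at 251 ± 5.2 and 206 ± 7.8 CPM (-0.28, edgeR adjusted p = 0.255), and PLK1 at 98.9 ± 0.69 and 87.7 ± 4.5 CPM (-0.17, edgeR adjusted p = 0.514). EIF4A1 (-0.18, edgeR adjusted p = 0.379), EIF4A2 (-0.031, 0.951) and UGT2B15 (-0.20, 0.775) did not pass either.

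An unadjusted p under 0.05 was reached by 1583 genes (9.76%) in this comparison, so the count of 1 is tied to the adjustment. It also moved with the method and with the libraries used. DESeq2 called 72 genes and edgeR without a filter on low counts called 142. Leaving out S239A replicate 2 alone kept the count at 1, leaving out S239D replicate 2 gave 8 and leaving out WT replicate 3 gave 2. Leaving out S239A replicate 2 and S239D replicate 2 together, chosen after seeing their mitochondrial shares, gave 874 genes (442 higher and 432 lower in S239A), TXNIP among them. MYC passed with that setting (-0.26, edgeR adjusted p = 0.00443) and with DESeq2 (-0.28, adjusted p = 0.0389), and its adjusted p ran from 0.00443 to 0.713 over the alternatives. EIF4A1 passed with that setting as well (-0.20, edgeR adjusted p = 0.0051, range over the alternatives 0.0051 to 0.763).

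Gene lists fixed before the data were examined showed small shifts in S239A. Of 32 lists tested with camera, 9 were called, 4 higher and 5 lower than in WT. Targets of MYC, many of them nucleolar genes, were lower (68 measured, median log2 fold change -0.18, camera adjusted p = 1.2e-12). Genes of DNA replication were lower too (60 measured, median -0.17, camera adjusted p = 6.49e-10), and MCM4 and MCM5 belong to both lists. Both calls held with an estimated correlation between genes (adjusted p = 0.023 and 0.0237). Over all genes tested no member of any list was called. Adjusted over the list alone, 9 MYC targets fell and 0 rose, and 0 DNA replication genes changed. Androgen-induced genes were not called as a list (camera adjusted p = 0.695), with 4 higher and 2 lower of 45 adjusted over the list alone. Nor were the 12 androgen-repressed genes (1 higher and 0 lower, camera adjusted p = 0.941) or the 43 AP-1 and immediate early genes (4 and 4, camera adjusted p = 0.112).

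The other 7 called lists lost the call with an estimated correlation. Lower in S239A were mitosis genes (median -0.12, camera adjusted p = 5.39e-05, and adjusted p = 0.277 with an estimated correlation), hypoxia and glycolysis genes (-0.13, camera adjusted p = 3.49e-05, then adjusted p = 0.074 with an estimated correlation) and nuclear-encoded genes of oxidative phosphorylation (-0.077, camera adjusted p = 0.000201, then adjusted p = 0.457 with an estimated correlation). Higher were the 13 mitochondrially encoded transcripts (median 0.42, camera adjusted p = 1.21e-08, then adjusted p = 0.277 with an estimated correlation) and cell adhesion and axon guidance genes (0.14, camera adjusted p = 0.00164, then 0.277 with an estimated correlation). TGF-beta response genes (0.073, camera adjusted p = 0.025, then adjusted p = 0.277 with an estimated correlation) and epithelial junction and luminal keratin genes (0.048, camera adjusted p = 0.0383, then adjusted p = 0.387 with an estimated correlation) were higher as well. Adjusted over the list alone, 6 mitochondrially encoded transcripts rose, 3 hypoxia and glycolysis genes fell and 1 mitosis gene fell, with 0 changed in the remaining 4 lists. Without S239A replicate 2, the library with the highest mitochondrial share of its group, the mitochondrially encoded median was 0.14 (camera adjusted p = 0.0192, range over alternatives 3.29e-15 to 0.277) and the oxidative phosphorylation median turned to 0.025 (camera adjusted p = 0.969, range 3.56e-10 to 0.969). The adhesion, TGF-beta and epithelial junction calls were lost without that library too, the TGF-beta and epithelial junction calls also without WT replicate 3 or S239A replicate 1, and the epithelial junction call also without WT replicate 1.

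The comparison of S239D with WT asks what a phosphate mimic at the site does, and a large part of the transcriptome differed. Against WT, 6708 of 16213 genes passed the edgeR test (41.4%), 3195 higher and 3513 lower, of which 609 and 1170 changed at least 2-fold. UGT2B15, which encodes an enzyme that inactivates androgens by glucuronidation, had the largest rise among genes with a symbol, a mean of at least 5 CPM and no overlap between the libraries of the groups, from 7.47 ± 1.2 to 51.7 ± 7.0 CPM. The lists of neuroendocrine, hypoxia and glycolysis, DNA replication and interferon response genes were called lower and that of p53 targets higher, with and without an estimated correlation. MYC fell by 0.44 on the log2 scale (SE 0.076, edgeR adjusted p = 0.000387), from 251 ± 5.2 to 185 ± 10 CPM (SD, n = 3).

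UGT2B15 (chromosome 4, 68646597 to 68670652) rose by a log2 fold change of 2.81 (SE 0.16, edgeR adjusted p = 2.56e-08). It belongs to a family of near-identical genes that can share reads, so its value is uncertain to that extent, as is that of the metallothionein MT1G. Other large rises were those of LAMA3, a laminin chain (2.69), LAT, a T-cell signalling adaptor (2.59), IZUMO1, a sperm fusion protein (2.49), MT1G (2.47), TNFAIP3, an inhibitor of NF-kB signalling (2.37), NR4A3, an orphan nuclear receptor (2.37), and KCNH5, a potassium channel (2.22). These genes lay between 2.04 and 5.61 CPM in WT, and their edgeR adjusted p ran up to 1.55e-05 for KCNH5. TNFAIP3 did not pass with limma on log2(TPM + 1) (0.69, adjusted p = 0.0852), and LAMA3 lies on chromosome 18, where genes were higher in S239D as a whole (median log2 fold change 0.21). The largest falls by the same rule were those of RIPOR2 (-4.12, from 11.1 to 0.637 CPM, with S239D replicate 3 at its floor of 0.315 CPM), SUSD2 (-3.78), FAIM2 (-3.70), the prostaglandin receptor gene PTGER3 (-3.55, from 134 ± 9.8 to 11.4 ± 1.8 CPM), the Hedgehog effector GLI1 (-3.54), the long noncoding RNA TUNAR (-3.54), MFAP2 (-3.26) and DGKG (-3.07). PTGER3 lies on chromosome 1 (70852353 to 71047808) and GLI1 on chromosome 12 (57459785 to 57472268). EIF4A1 was lower (-0.21, edgeR adjusted p = 0.0198), a call lost without any 1 WT library or without S239D replicate 3 (edgeR adjusted p = 0.0616 to 0.0697). The EIF4A1 call was also lost without a filter (edgeR adjusted p = 0.0552), with GC and length trends removed (-0.13, 0.128) and with limma on log2(TPM + 1) (-0.039, 0.743), and its adjusted p ran from 0.000297 to 0.743 over the alternatives. EIF4A2 (0.15, edgeR adjusted p = 0.233) and PLK1 (-0.094, edgeR adjusted p = 0.378) did not pass.

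**Figure D2:**
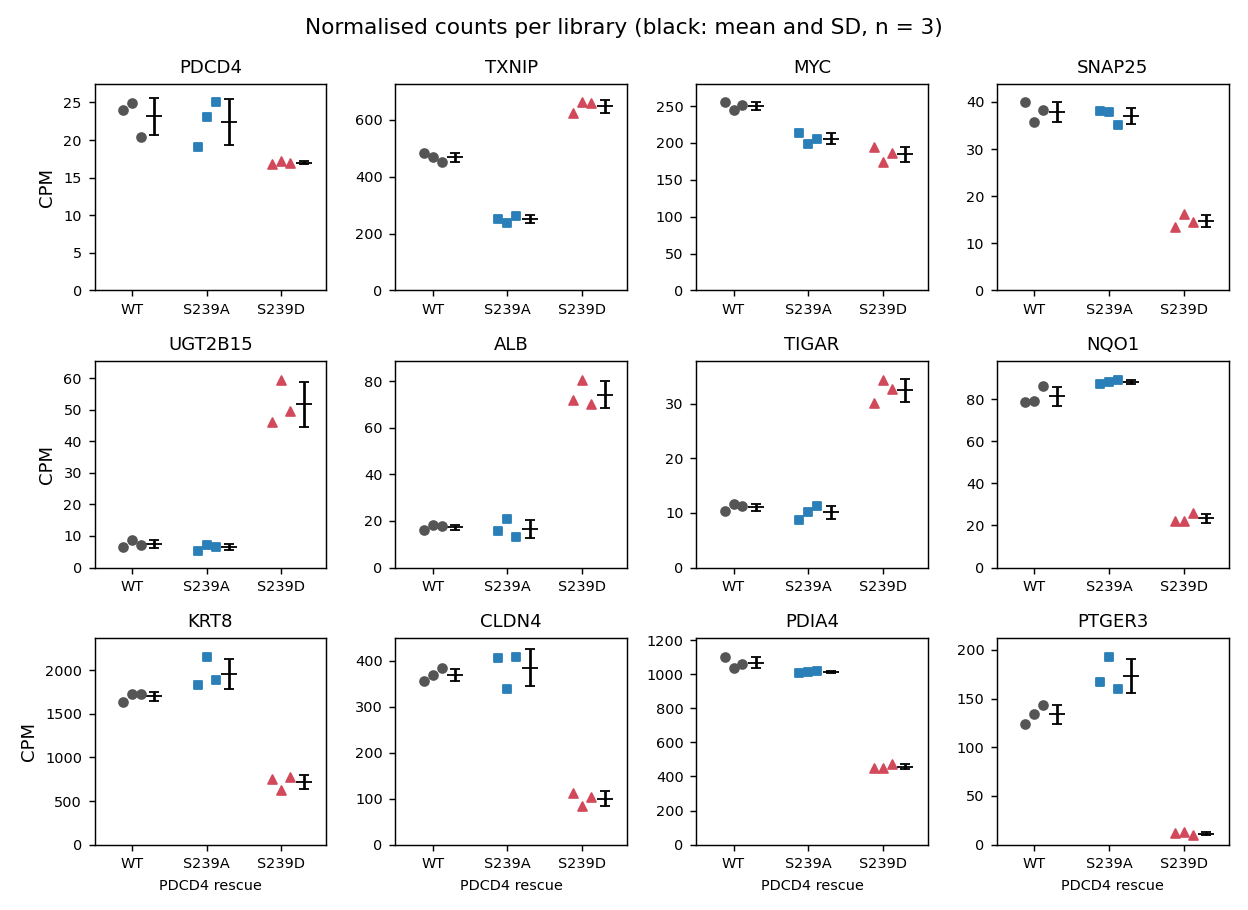
Normalised counts (CPM, y axis from 0) of 12 named genes in each library of WT, S239A and S239D (x axis), with the mean and SD of the 3 libraries in black. UGT2B15 averages 7.47, 6.41 and 51.7 CPM in the 3 groups, and TXNIP averages 468, 251 and 647 CPM.

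Cell cycle genes were lower in S239D than in WT. Of 62 mitosis genes, 42 fell and 0 rose (44 and 0 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 2.7e-11, adjusted p = 0.0943 with an estimated correlation). Among them were PTTG1, the securin gene (-1.05, SE 0.10), the kinase gene PBK (-0.94), the mitotic kinesin gene KIF20A (-0.93) and the spindle gene NUSAP1 (-0.88). Of 60 DNA replication genes, 44 fell and 2 rose (47 and 2 adjusted over the list alone), with a median of -0.42 (camera adjusted p = 2.96e-09, adjusted p = 0.0174 with an estimated correlation). GINS2, part of the replicative helicase, fell by 0.96, RFC2 by 0.77, the thymidine kinase gene TK1 fell by 0.75 and RRM2, of ribonucleotide reductase, fell by 0.70. MYC targets went both ways, 17 rose and 11 fell of 68, with the same counts adjusted over the list alone, and were not called (camera adjusted p = 0.13).

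Ribosomal protein and mitochondrial transcripts moved in opposite directions. Of 79 cytosolic ribosomal protein genes, 65 fell and 0 rose (70 and 0 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 8.43e-15, adjusted p = 0.168 with an estimated correlation). RPL10A fell by 0.70, RPS15A fell by 0.68 and RPS6 fell by 0.64. These genes have many processed pseudogenes, with which reads can be shared. All 13 mitochondrially encoded transcripts were measured, of which 12 rose and 0 fell, over all genes and adjusted over the list alone (median 0.97, camera adjusted p = 1.63e-06, adjusted p = 0.263 with an estimated correlation). The mitochondrial share of counts was highest in S239D replicate 2 (6.01%). MT-ND6 rose by 1.65 (SE 0.20), MT-ND4L by 1.22, MT-ATP6 by 1.12 and MT-ND3 by 0.97. Of 76 nuclear-encoded genes of oxidative phosphorylation, 23 fell and 4 rose, with the same counts adjusted over the list alone (median -0.19, camera adjusted p = 0.04, adjusted p = 0.749 with an estimated correlation). The examples with the smallest adjusted p were NDUFB6 (-0.77), COX5A (-0.70), NDUFA4 (-0.60) and SDHB (-0.44). That list was not called without WT replicate 3 (camera adjusted p = 0.0652) or without S239D replicate 2 (camera adjusted p = 0.224, range over alternatives 0.00857 to 0.749).

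Of 25 neuroendocrine and neuronal genes, 21 fell and 2 rose (21 and 3 adjusted over the list alone), with a median of -0.99 (camera adjusted p = 6.49e-09, adjusted p = 0.0158 with an estimated correlation). SNAP25, of the synaptic vesicle fusion machinery, fell by 1.37 (SE 0.11), the granin gene CHGB fell by 1.0, SEZ6 fell by 0.99 and the neuronal tubulin gene TUBB3 fell by 0.79. Of 43 epithelial junction and luminal keratin genes, 22 fell and 2 rose (23 and 3 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 2.57e-05, adjusted p = 0.164 with an estimated correlation). The tight junction genes CLDN4 (-1.88, from 370 ± 14 to 100 ± 15 CPM), CLDN3 (-1.46) and TJP3 (-1.20) and the luminal keratin gene KRT8 (-1.25, chromosome 12, 52897187 to 52949954) were among them. Of 37 Wnt and beta-catenin targets, 16 fell and 4 rose, with the same counts adjusted over the list alone (median -0.50, camera adjusted p = 0.00665, adjusted p = 0.0943 with an estimated correlation). NOTUM (-2.78) and RNF43 (-1.86), both feedback inhibitors of Wnt signalling, fell with the receptor gene FZD1 (-0.68), while TNFRSF19 rose (0.75).

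Stress and metabolic lists were called as well. Of 46 hypoxia and glycolysis genes, 30 fell and 2 rose (31 and 2 adjusted over the list alone), with a median of -0.46 (camera adjusted p = 6.49e-09, adjusted p = 0.0174 with an estimated correlation). EGLN3, an oxygen-sensing hydroxylase, fell by 1.77, the glycolytic genes PGK1 and ENO2 fell by 0.84 and 0.82, and NDRG1 fell by 0.80. Of 38 endoplasmic reticulum chaperone genes, 19 fell and 3 rose, with the same counts adjusted over the list alone (median -0.27, camera adjusted p = 0.000164, adjusted p = 0.0943 with an estimated correlation), among them PDIA4 (-1.22), HSP90B1 (-0.96), CALR (-0.83) and PDIA3 (-0.81). Of 36 NRF2 and xenobiotic response genes, 13 fell and 4 rose, with the same counts adjusted over the list alone (median -0.23, camera adjusted p = 0.00695, adjusted p = 0.105 with an estimated correlation). The antioxidant genes NQO1 (-1.80), ME1 (-1.43), TXNRD1 (-0.96) and GCLC (-0.94) were lower. Of 41 interferon response genes, 20 fell and 6 rose, with the same counts adjusted over the list alone (median -0.54, camera adjusted p = 0.000876, adjusted p = 0.0339 with an estimated correlation). BST2 (-2.16), HLA-B (-1.67) and IFITM2 (-1.60) were lower, the HLA and IFITM genes being families with shared reads. Of 38 p53 targets, 20 rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 3.48e-05, adjusted p = 0.0305 with an estimated correlation). TIGAR rose by 1.56, BTG2 by 1.47 and XPC by 0.95, while the autophagy gene DRAM1 fell by 1.63. XPC lies on chromosome 3, where genes were higher in S239D as a whole (median 0.23), and TIGAR did not pass with limma on log2(TPM + 1) (0.77, adjusted p = 0.187). Of 27 cholesterol synthesis genes, 11 rose and 0 fell, with the same counts adjusted over the list alone (median 0.26, camera adjusted p = 0.00224, adjusted p = 0.0706 with an estimated correlation), among them SQLE (0.70), IDI1 (0.57) and the regulator SREBF2 (0.45).

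Of 32 lists, 14 were thus called for S239D against WT, 3 higher and 11 lower, and the 5 calls of DNA replication, hypoxia, neuroendocrine, interferon and p53 genes held with an estimated correlation. No called list changed the sign of its median with RLE scaling, DESeq2, limma on log2(TPM + 1), either other filter or trends removed, but with limma several medians were smaller, such as that of interferon response (-0.34). Androgen-induced genes went both ways, with 10 higher and 13 lower of 45 (10 and 15 adjusted over the list alone, camera adjusted p = 0.345), as did the 12 androgen-repressed genes, with 4 higher and 4 lower (5 and 6 adjusted over the list alone, camera adjusted p = 0.345). Of 13 glucuronidation genes, 2 rose and 7 fell, with the same counts adjusted over the list alone (median -0.41, camera adjusted p = 0.564). The rise of UGT2B15 was thus not shared by the list as a whole, which also holds genes outside the UGT2B family. With limma on log2(TPM + 1), 4351 genes were called, of which 58.1% were higher, against 47.6% in the edgeR test.

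**Figure D3:**
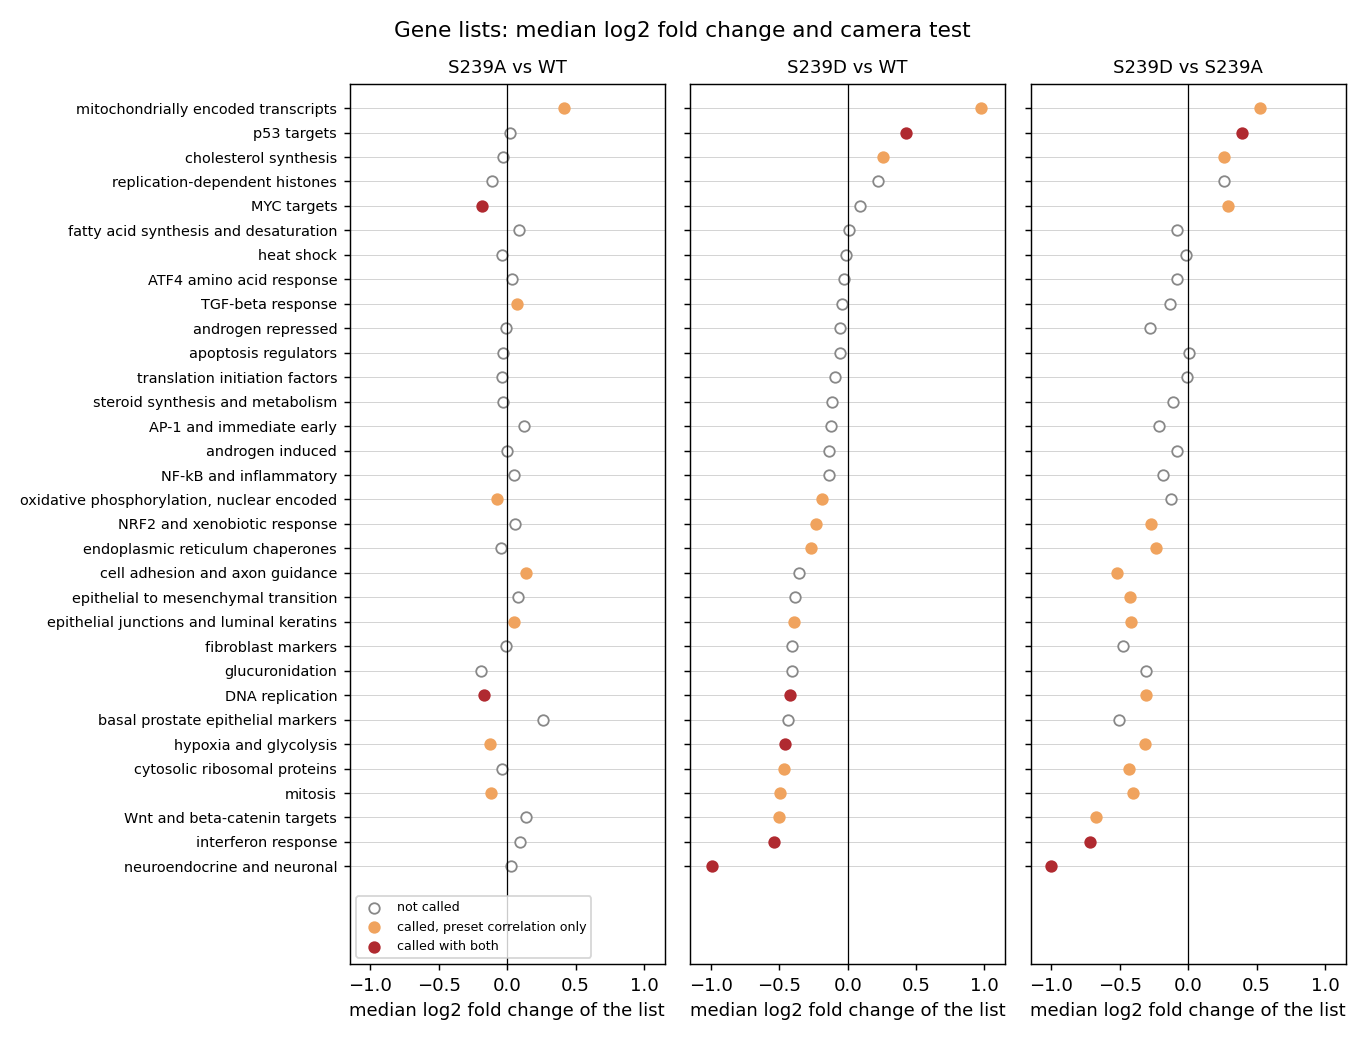
Median log2 fold change (x axis) of each of the 32 lists tested (y axis) in the 3 comparisons; open circles were not called by camera, orange circles were called with the preset correlation only, and red circles also with an estimated correlation. The neuroendocrine and neuronal list has the lowest median against WT in S239D (-0.99) and the mitochondrially encoded transcripts the highest (0.97).

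Along the chromosomes, genes of chromosomes 3 and 18 lay higher in S239D, a pattern chosen after its values were seen. The 869 genes of chromosome 3 had a median log2 fold change of 0.23 against WT and the 232 genes of chromosome 18 one of 0.21, with 66.3% and 68.5% of genes higher. A permutation test that shuffled genes between chromosomes and took the largest median gave p = 0.001 for each, the smallest the shuffles can give. This shuffle treats genes as independent replicates and holds no spread between libraries. In S239D against WT, medians of windows of 50 neighbouring genes had an SD of 0.143, against at most 0.0901 with gene order shuffled. All permutation p-values given here can therefore be too small, and they do not measure replication. The same chromosomes had medians of -0.011 and -0.035 in S239A against WT, where chromosome 21 lay lower (-0.046, permutation p = 0.011). Chromosome 8 also lay higher in S239D than in WT (0.12, permutation p = 0.014) and than in S239A (0.11, permutation p = 0.03). Chromosomes 16 (0.10, permutation p = 0.045) and 21 (0.11, permutation p = 0.033) lay higher than in S239A. With GC and length trends removed, chromosomes 18 (-0.041, permutation p = 0.008) and 19 (0.036, permutation p = 0.025) passed too in S239A against WT. Chromosomes 4 (-0.099, permutation p = 0.038), 13 (-0.11, permutation p = 0.023) and 16 (0.11, permutation p = 0.023) then passed too in S239D against WT.

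**Figure D4:**
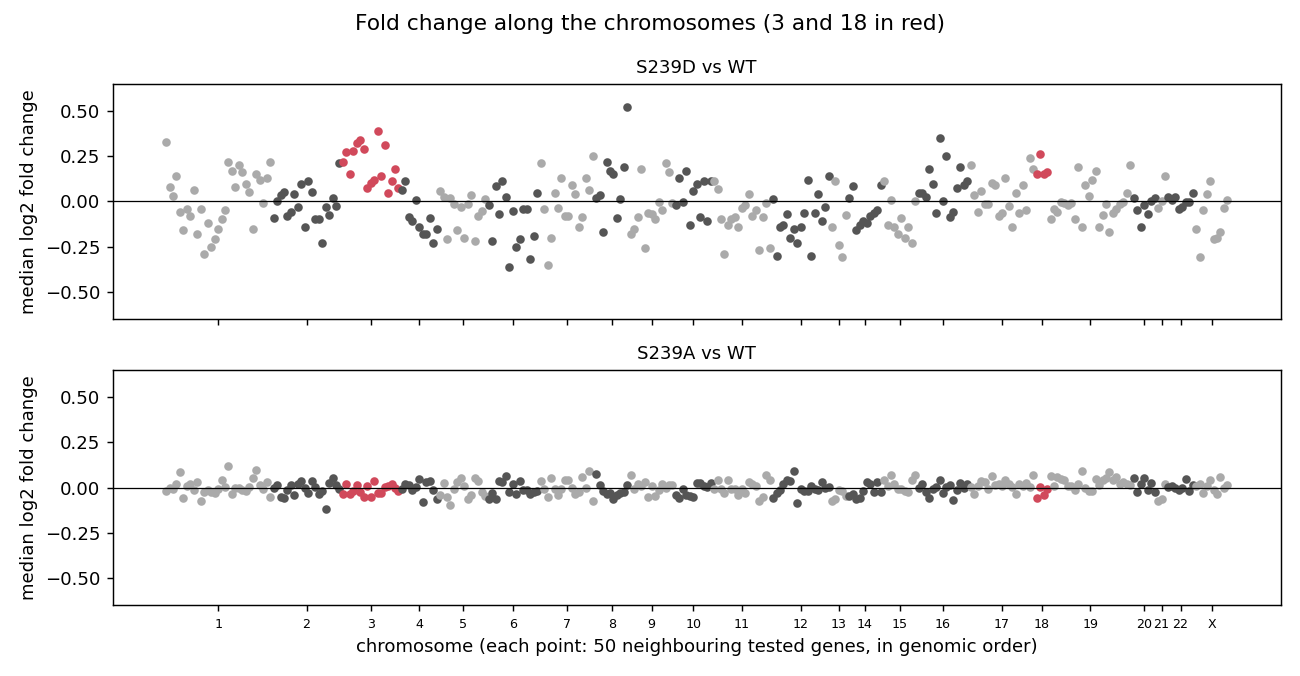
Median log2 fold change (y axis) of windows of 50 neighbouring tested genes in genomic order (x axis), for S239D against WT (top) and S239A against WT (bottom), with chromosomes 3 and 18 in red. All 21 windows on those chromosomes lie above 0 in S239D, from 0.044 to 0.39, and 9 do in S239A.

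The direct comparison of the variants tests whether their libraries differ. It cannot separate the variant itself from other differences between the lines, such as the PDCD4 level. S239D differed from S239A in 7064 of 16213 genes, 3390 higher and 3674 lower, of which 601 and 1359 changed at least 2-fold. UGT2B15 was again among the largest rises (3.01, SE 0.16, edgeR adjusted p = 1.14e-08), with LAT (3.01), MT1G (2.91), IZUMO1 (2.80), EFCAB2 (2.51), ANKRD29 (2.49) and the deiodinase gene DIO2 (2.40). RIPOR2 (-4.28), FAIM2 (-3.97), PTGER3 (-3.93), the collagen genes COL9A2 (-3.86) and COL12A1 (-3.71), GLI1 (-3.75), SUSD2 (-3.73) and DGKG (-3.70) had the largest falls. TXNIP was higher in S239D (647 ± 22 CPM) than in S239A (251 ± 13 CPM), by a log2 fold change of 1.37 (edgeR adjusted p = 1.67e-08). SMN2 was called higher (edgeR adjusted p = 0.0306), but it was at 0 CPM in S239A replicates 1 and 3, has a near-identical copy, SMN1, and the call was lost without S239A replicate 1, S239A replicate 3, S239D replicate 2 or S239D replicate 3, with DESeq2 and with limma on log2(TPM + 1) (adjusted p from 1.72e-18 to 0.363 over the alternatives).

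Of the 32 lists, 16 were called between the variants, 4 higher and 12 lower in S239D. MYC targets were higher in S239D than in S239A, with 37 higher and 4 lower of 68 (38 and 4 adjusted over the list alone), a median of 0.29 and a camera adjusted p of 0.000112 (adjusted p = 0.0629 with an estimated correlation). The ribosome assembly genes RRP9 (1.04), NOP2 (0.79) and GNL3 (0.70) and the coactivator gene PPRC1 (0.77) were examples, of which RRP9 and GNL3 lie on chromosome 3. MYC itself did not pass between the variants (-0.16, edgeR adjusted p = 0.108). Neuroendocrine and neuronal genes (median -1.0, 20 lower and 2 higher, 21 and 2 adjusted over the list alone), interferon response genes (-0.71, but -0.30 with limma on log2(TPM + 1) and -0.49 with the stricter filter, 22 lower and 5 higher by both counts) and p53 targets (0.39, 23 higher and 4 lower by both counts) held with an estimated correlation (adjusted p = 0.0125, 0.0351 and 0.0351). SRRM4, a neuronal splicing regulator, fell by 0.95, and PARP9 on chromosome 3 rose by 0.94.

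Epithelial to mesenchymal transition genes and cell adhesion and axon guidance genes were called lower in S239D than in S239A, and both calls were lost with an estimated correlation (adjusted p = 0.134 and adjusted p = 0.214). Against WT their medians in S239D were -0.39 and -0.36 without a call (camera adjusted p = 0.0946 and 0.0927). Of 41 transition genes, 16 were lower and 8 higher (17 and 8 adjusted over the list alone, camera adjusted p = 0.0384), among them TGM2 (-2.08), FN1, the fibronectin gene (-1.34), and CD44 (-1.06), and the call was lost without S239D replicate 2 (camera adjusted p = 0.0588). Of 43 adhesion and guidance genes, 26 were lower and 7 higher by both counts (camera adjusted p = 0.00425), with CNTN1 (-3.26) and SEMA6D (-2.50) lower and SEMA6A (1.0) and EPHA3 (1.17, on chromosome 3) higher. Calls were lost in the same way for mitosis (adjusted p = 0.151 with an estimated correlation), DNA replication (0.0783), ribosomal proteins (0.211), mitochondrially encoded transcripts (0.499), hypoxia and glycolysis (0.0515), cholesterol synthesis (0.0515), endoplasmic reticulum chaperones (0.146), NRF2 response (0.084), epithelial junctions and keratins (0.11) and Wnt targets (0.0515). With limma on log2(TPM + 1), 4697 genes were called between the variants, of which 59.3% were higher, against 48.0% in the edgeR test.

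The effects of S239A and S239D against WT were then set side by side. The 1 gene called for S239A, TXNIP, was also called for S239D in the opposite direction, with a log2 fold change of -0.90 in S239A and 0.47 in S239D (edgeR adjusted p = 0.000188). Independent lists of these sizes would share 0.41 genes, and simulated unchanged groups against the same simulated WT libraries shared at most 1. The overlap was 53 genes with DESeq2, 89 without a filter, 19 with GC and length trends removed, 2 without WT replicate 3, 6 without S239D replicate 2 and 624 without S239A replicate 2 and S239D replicate 2 together. Across 12559 genes with at least 5 CPM, which are not independent replicates, the log2 fold changes of the variants had a correlation of -0.013 and the same sign in 53% of genes. Their covariance was -0.00132, below the 0.0121 to 0.0158 that sharing the WT libraries gave in 20 simulated sets of unchanged groups. The simulation used a spread per gene shared over the groups. Chi-square per degree of freedom between library pairs was 1.9 to 2.27 within WT. It was 9.22 to 15.9 for the variants' replicate 2 libraries within their groups. Sharing WT may thus give a smaller covariance than simulated, so no opposed effects are read from this. Both variants lay below WT in MYC, with 206 ± 7.8 and 185 ± 10 against 251 ± 5.2 CPM, although the S239A difference did not pass.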

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

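Leaving out both replicate 2 libraries of the variants, removing GC and length trends, and thinning to one total were tests chosen only after the results were seen. Most named genes were picked for large changes or small adjusted p in these libraries, so how often they held does not speak for other genes. Across 19 alternatives, named genes gave 3457 values with the direction and side of the threshold kept, 66 no longer past it, 5 newly past it and 4 reversed. List tests gave 1244, 53, 45 and 2 over 14 settings, which leave out DESeq2, limma on TPM, the filters, fits of the compared groups alone, trend removal and thinning. A list called neither in the main test nor in the setting counted as kept, whatever its direction. Medians of lists were also computed with RLE, DESeq2, limma on TPM, the 2 filters and trends removed. Those of called lists kept their sign there and those of some other lists did not. With limma on TPM several called lists had smaller medians between the variants, such as interferon response (-0.71 to -0.30), DNA replication (-0.31 to -0.14), NRF2 response (-0.27 to -0.12) and cell adhesion (-0.52 to -0.27). In S239A against WT, removing trends moved oxidative phosphorylation from -0.077 to -0.046 and cell adhesion from 0.14 to 0.079. It moved mitochondrially encoded transcripts from 0.42 to 0.52, and limma on TPM moved oxidative phosphorylation to -0.12. For S239A against WT, the count of 1 gene was 72 with DESeq2, 2 with limma on TPM, 142 without a filter, 23 with GC and length trends removed, 874 without both replicate 2 libraries, and 1 to 8 with each library left out. Its overlap of 1 with S239D was 53 with DESeq2, 89 without a filter, 19 with trends removed, 624 without both libraries and 1 to 6 with each library left out. With limma on TPM, S239D differed from WT in 4351 genes and from S239A in 4697, and leaving out each library gave 5322 to 7533 and 5853 to 7182. Called lists numbered 2, 5 and 3 with an estimated correlation, and 3 and 23 with fry for S239A and S239D against WT. PDCD4 in S239A against WT was -0.13 to 0.063 with each library left out and 0.0056 with trends removed, and DESeq2 gave it no adjusted p. In S239D against WT it was -0.29 with limma on TPM (range when leaving out a library -0.53 to -0.39), and against S239A -0.40 with DESeq2 and -0.20 with limma on TPM (range -0.50 to -0.31). Reversed were EIF4A2 in S239A against WT (-0.083 to 0.059 with each library left out, 0.057 without both), the oxidative phosphorylation list there (-0.17 to 0.025, 0.026 without both), and EIF4A1 in S239D against S239A (0.12 with limma on TPM, 0.0055 without both). With replicate number as a block, 6 genes were called for S239A and 4 overlapped. Whether the numbers pair the libraries stays open. Deviations from the group means correlated at 0.10, 0.25 and 0.10 between same-number libraries of S239A and S239D, and at -0.21 to 0.15 between different numbers. The 0.15 was S239A replicate 3 with S239D replicate 1, above its own number (0.10). Same-number pairs with WT ran from -0.0087 to 0.091. The cause of the shifts between alternatives was not tested. Depth limits genes near the floor of 0.307 to 0.527 CPM.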

Other observations

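Tests chosen only after the result was seen were thinning, the removal of GC and length trends, the split counts for S239D, the direction of called genes within windows and both tests on chromosomes 3 and 18. Markers of other cell types moved apart in S239D against WT. ALB, the serum albumin gene, rose from 17.4 ± 1.1 to 74.2 ± 5.6 CPM (SD, n = 3; edgeR adjusted p = 1.21e-07), 1 of 4 measured hepatocyte markers to rise, with 0 falling. Of 8 basal prostate epithelial markers 3 rose and 4 fell, with the same counts adjusted over the list alone. SNAI2 (1.18) was higher and NGFR (-2.48) and LAMB3 (-1.79) lower. Of 6 fibroblast markers 1 rose and 2 fell, also adjusted over the list alone, with DCN (-2.22) and LUM (-0.90) lower, the LUM call being lost with limma on log2(TPM + 1) (adjusted p = 0.0554, range over alternatives 4.08e-09 to 0.0554). Of 2 leukocyte markers 0 rose and 1 fell by both counts, and of 2 endothelial markers 0 rose and 1 fell (1 and 1 adjusted over the list alone), ESAM (-2.22).

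Several other lists were not called by camera in S239D against WT. Counts that rose and fell were 3 and 7 of 19 steroid synthesis and metabolism genes, 6 and 8 of 30 NF-kB genes and 6 and 9 of 35 TGF-beta response genes, each the same adjusted over the list alone. They were 13 and 16 of 43 AP-1 and immediate early genes (14 and 17 adjusted over the list alone), 8 and 14 of 41 epithelial to mesenchymal transition genes (8 and 17) and 9 and 22 of 43 cell adhesion and axon guidance genes (11 and 24). Of 15 replication-dependent histone genes 5 rose and 0 fell by both counts. Counts were 7 and 9 of 46 translation initiation factors (6 and 9 adjusted over the list alone), 5 and 11 of 27 fatty acid synthesis genes (7 and 12), 9 and 11 of 44 ATF4 response genes (9 and 12), 4 and 3 of 29 heat shock genes (4 and 2) and 7 and 8 of 42 apoptosis regulators (7 and 7). Median, mean and test differed in sign for androgen-repressed, fatty acid and TGF-beta genes in S239D against WT. They also did for androgen-induced, androgen-repressed and fibroblast genes in S239A against WT. Between the variants they did for androgen-repressed, glucuronidation, translation initiation, heat shock and apoptosis genes.

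The 6708 genes that differed between S239D and WT were set against technical explanations. With all libraries thinned to 5696841 counts, 88.0% of the called genes were called again in the same direction, and with GC and length trends removed 95.1% were, which argues against depth or those trends as the whole cause. Copy number differences between the lines cannot be told apart from regional effects of expression. Medians beyond 0.3 were found in 4.23% of windows of 50 neighbouring genes. Shuffled gene order gave at most 0.651%, and S239A against WT gave 0%. The upper limit of 7.13% on the share keeps copy number differences open, and it treats windows as independent. Shifts smaller than 0.3, such as the medians of 0.23 and 0.21 on chromosomes 3 and 18, are not counted in these shares. Of the called genes, 34.2% moved against the majority of the called genes in their window (lower limit 32.9%). A change of copies shared by a whole window would not by itself move genes in opposite directions. The share that directions unrelated to position would give was not computed, and the cut for this test was set after the results were seen. This share therefore cannot decide how much of the change follows copy number. Whether the variant or another difference between the lines, such as the lower PDCD4 level in S239D, underlies the change stays open.

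The 10 splits of 6 libraries are too few for a share under 0.05. For S239A against WT, 6 of 10 splits called as many genes as the real one (1), and the highest other called 3. For S239D the real split was 1 of 10, with 6950 genes against WT and 5950 against S239A, and the highest other called 0 in both. Every other split puts libraries of both groups on each side. Where the groups differ widely this raises the spread within each side, so the 0 calls are no yardstick for the real counts.

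The higher level of genes on chromosomes 3 and 18 in S239D kept a median of at least 0.17 with GC and length trends removed, which argues against those trends as the whole cause. A gain of copies stays open: 100% of the 21 windows on these chromosomes lay above 0 against both WT and S239A, but the chromosomes were picked for their high medians and both comparisons share the S239D libraries, so this does not test it. The files used here hold no DNA measurements, and regional regulation of expression was not tested.

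UGT2B15 is part of a family whose members can share reads. The summed counts of the UGT2B genes were 4.49-fold higher in S239D than in WT (lower 95% limit 3.03), at 52.9 to 67.2 against 12 to 14.6 CPM per library, which argues against reads moved between these genes as the cause. The rise may therefore reflect more transcript from the family, most of it assigned to UGT2B15 (1330 of the S239D counts, 173 of those of WT). Unscaled counts summed per group were also higher in S239D than in WT for UGT2B10 (71 against 30) and UGT2B11 (39 against 19). The same held for UGT2B17 (30 against 10) and UGT2B7 (12 against 7). They were lower for UGT2B4 (29 against 60) and UGT2B28 (5 against 7). Whether the variant or another difference between the lines underlies the rise of UGT2B15 was not tested.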
